A study of Homo sapiens with 6 samples.

How the data were processed

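Total RNA from HEK293T cells was extracted with Trizol and labelled with Cyanine 3-pCp by an Agilent miRNA labelling kit, per the labels, and measured on 1-colour Agilent human miRNA arrays. The 6 samples fall into 2 groups of 3 by their labels, vehicle and 99021, numbered 1 to 3 in their titles. Dose and duration of treatment are not given in the sources used here.

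Per the file headers, spot intensity was read with Agilent Feature Extraction 10.7.3.1, which subtracted background with spatial detrending and marked outlier spots. The deposited intensity values are not scaled between arrays and can be negative. The deposited series table holds the same background-subtracted intensity rounded to 3 significant digits, on 100% of the 56044 spots of every array and in the same direction. Its scale is thus linear and uncentred, and its column medians were 0.602, 0.174 and 0.465 in vehicle replicates 1 to 3 and 0.00439, 0.283 and -0.804 in 99021 replicates 1 to 3. All 6 arrays lay on 1 slide and were scanned in 1 scan, so neither could act as a batch. No spot was saturated.

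Of the 56044 spots, 48200 belong to 3101 probes of 1205 human entries, 2164 are controls and the rest belong to 142 viral entries. Control and viral spots and spots with outlier marks were left out. A probe, with 10 to 40 spots, was called detected where at least 50% of its remaining spots were well above background. The background-subtracted intensity was averaged over a probe's spots and divided by the array's 75th percentile over the 166 probes detected on all arrays, which ranged from 198 to 354. Values were floored at the lowest scaled value of a detected probe (0.0502, reached by 6 values) and taken to log2. Probes detected on all arrays of at least 1 group were kept (228 probes of 144 miRNAs), and a miRNA was the mean log2 value of its kept probes. Probes of 83 miRNAs could be compared, and in 4 they differed in sign, none of them a miRNA that the rule below names. Fold values are therefore relative to each array's bright probes, and a change shared by all miRNAs is not visible in them. Names are those of the array design; 6 tested entries carry names since withdrawn, which are written without their version suffix. Positions are hg19 probe positions from the array files, given where the files list 1 position (80 of 144 miRNAs). No annotation of that build was used here, so gene context is background knowledge.

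Groups were compared with limma 3.58.1 (lmFit and eBayes, no covariate) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 144 miRNAs and a threshold of 0.05. Figures were drawn with matplotlib 3.10.9. The 22 lists were written before the data were examined, and the 12 with at least 3 tested entries were compared with all other miRNAs by camera with a preset correlation of 0.01, with camera at an estimated correlation beside it. fry tested each list against no change. All 3 were adjusted over the lists. Single values per array were compared with an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3. The rule for naming miRNAs, also written before, took up to 12 per direction among those past the threshold without overlap, filled each direction to 6 by unadjusted p, and added the 2 brightest of each list and the 5 brightest of all. It named 41 miRNAs, and others are marked where they occur.

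The steps were tested on simulated data built from 1 vehicle array with the observed spread, 157 miRNAs and 20 runs per design. With no changed miRNA, 0 of 3140 tests were called. With 12 changed miRNAs per run, 30% of log2 changes of 0.5, 86.2% of 1 and 97.5% of 1.5 were recovered, and 14 of 2900 unchanged miRNAs were called. With 42 changed, 70 of 2300 unchanged miRNAs were called, because the changes moved the 75th percentile and shifted the unchanged ones by -0.10 on average. For the lists, 0 of 260 tests of unchanged lists passed under either correlation; a shift of 0.4 in the fragment list passed in 20 of 20 runs with the preset and in 3 of 20 with the estimated correlation. The simulated noise was independent between miRNAs, which real noise is not. The array used was vehicle replicate 1, whose negative control probes varied most, and its detection and outlier marks were copied to all 6 simulated arrays. Differences in detection between arrays, and their effect on the filter and the percentile, were thus not simulated.

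Alternatives were other scalings (75th percentile over all human probes, none, spike-ins, hur control probes, quantile), normexp background correction with an offset of 50, other summaries (total gene signal, brightest probe, series table), other filters, eBayes with trend and robust, each array left out, the replicate number as a block, and the letter in the array name as a random block. A fixed letter block, the slide row as a block and removal of a GC trend were added after seeing the data.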

Results

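MicroRNAs of HEK293T cells, a human embryonic kidney line, were profiled after treatment with an inhibitor that the labels call 99021 or with its vehicle. The study's title concerns GSK3B, a serine/threonine kinase, and the Microprocessor, the nuclear complex in which the RNase Drosha cuts primary miRNA transcripts into hairpin precursors. Total RNA of 3 samples per treatment was labelled with Cyanine 3 and each sample was hybridised to 1 array of 1 slide, 6 arrays in all. The labels do not say whether the 3 samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Of 1205 human entries on the array, 154.7 ± 9.71 were detected per vehicle array and 144 ± 19.1 per 99021 array (SD, n = 3), and 144 entered the tests. Signals of the tested miRNAs correlated between arrays across miRNAs with r from 0.968 to 0.995. The array of 99021 replicate 3 stood apart, with 122 miRNAs detected against 144 to 163 on the other 5 arrays and a correlation of at most 0.981 with any of them. The array of vehicle replicate 1 differed in background, where its negative control probes had an SD of 19.7 against 3.6 to 5.3 on the other 5. The number of arrays limits the precision, and the median 95% confidence interval of a single miRNA reached 0.35 to either side on the log2 scale.

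The brightest entries were hsa-miR-720, hsa-miR-1274b, hsa-miR-20a-5p, hsa-miR-19b-3p and hsa-miR-4284. hsa-miR-720 and hsa-miR-1274b are names that overlap tRNA sequence and have been withdrawn from the miRNA catalogue, whereas hsa-miR-20a-5p and hsa-miR-19b-3p belong to the miR-17-92 cluster, an oncogenic group of miRNAs that promotes proliferation. Relative to vehicle, hsa-miR-20a-5p stood at 0.962-fold, hsa-miR-19b-3p at 0.931-fold and hsa-miR-4284 at 1.10-fold in the 99021 arrays, and none of these differences passed the test.

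The first comparison asked which miRNAs differed in level between inhibitor and vehicle. No single miRNA passed the threshold: 0 of 144 had an adjusted p under 0.05 in limma, where the smallest was 0.236, and 14 had an unadjusted p under 0.05, 7 higher and 7 lower in the 99021 arrays. The 3 values of each group did not overlap for 18 miRNAs, 7 higher and 11 lower, where chance gives 10% or 14.4. The largest difference of any miRNA was 0.72 on the log2 scale. The count was 5 with the letter in the array names as a random block. There hsa-miR-548f-3p, hsa-miR-548x and hsa-miR-1280 (limma adjusted p = 0.0251 each), hsa-miR-1260a and hsa-miR-4286 (both 0.0384) were higher. With the letter as a fixed block, a fit added after seeing the data, the count was 4. In that fit only the 2 vehicle and 99021 pairs that share a letter inform the difference. The SE was 0.21 for each of the 4, so these calls rest on 2 pairs and a shared SE.

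Among the 6 higher miRNAs of smallest unadjusted p, 3 were entries that overlap structural RNA. hsa-miR-4286 was at 1.49-fold of vehicle (log2 difference 0.57, SE 0.17, limma adjusted p = 0.236), hsa-miR-1280 at 1.49-fold (0.57, SE 0.18) and hsa-miR-1260a at 1.46-fold (0.54, SE 0.18). For each of these 3 entries the lowest 99021 array lay above the highest vehicle array. The probes of hsa-miR-1260a and hsa-miR-1280 both hold the stretch GGTGGCAG, so they may share signal. The other 3 belonged to the miR-548 family, primate-specific miRNAs that derive from a transposable element. hsa-miR-548f-3p was at 1.65-fold (0.72, SE 0.22), hsa-miR-548x at 1.63-fold (0.71, SE 0.23) and hsa-miR-548c-3p at 1.50-fold (0.58, SE 0.22), with overlapping groups in each case. The family's probes are A- and T-rich and much alike (AAAAGTAATTACAGTTTTT for hsa-miR-548f-3p and TGAAAGTAATTGCAGTTTTTA for hsa-miR-548x), so signal from one member on another's probe cannot be ruled out and the 3 values are uncertain as separate measurements. Without 99021 replicate 1, hsa-miR-548f-3p (0.86, limma adjusted p = 0.0152) and hsa-miR-548x (0.92, adjusted p = 0.00996) passed the threshold. Without 99021 replicate 3 hsa-miR-4286 did (0.81, limma adjusted p = 0.0499), a value that includes the shared shift. At the main scaling hsa-miR-4286 was at -0.04 and -0.01 on the other 99021 arrays, against a vehicle mean of -0.68. With each of the 6 arrays left out in turn, the difference of hsa-miR-548x ran from 0.59 to 0.92, that of hsa-miR-548f-3p from 0.59 to 0.96, hsa-miR-548c-3p from 0.43 to 0.86, hsa-miR-4286 from 0.41 to 0.81, hsa-miR-1280 from 0.41 to 0.75 and hsa-miR-1260a from 0.34 to 0.66. For each of these 6 miRNAs the lowest refitted value was the one without vehicle replicate 1, but the shared shift raised the values without 99021 replicate 3. On that array hsa-miR-548x was at -0.87, against -1.80 and -1.44 on the other 99021 arrays.

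The lower side was made up of conventional miRNAs. hsa-miR-26a-5p, a miRNA that restrains the cell cycle and EZH2, was at 0.708-fold of vehicle (log2 difference -0.50, SE 0.16, limma adjusted p = 0.236), and its close relative hsa-miR-26b-5p, on chromosome 2 at 219267382 to 219267400 (hg19, the probe's position as the array files give it), at 0.67-fold (-0.58, SE 0.19). hsa-miR-29a-3p, which targets collagen transcripts, was at 0.759-fold (chromosome 7, 130561550 to 130561568), hsa-miR-130b-3p at 0.766-fold (chromosome 22, 22007648 to 22007664) and hsa-miR-361-5p at 0.779-fold (chromosome X, 85045309 to 85045323). The groups did not overlap for these 5 miRNAs. hsa-miR-10a-5p, encoded in the HOXB cluster, was at 0.754-fold with overlapping groups (chromosome 17, 46657224 to 46657243). None of these passed the threshold over all 144 miRNAs. Refitted without 99021 replicate 3, hsa-miR-26b-5p was at -0.22, hsa-miR-26a-5p at -0.28 and hsa-miR-29a-3p at -0.25 against -0.40. hsa-miR-130b-3p was then at -0.28 against -0.38, hsa-miR-361-5p at -0.21 against -0.36 and hsa-miR-10a-5p at -0.41 as before. These refitted values include the shared shift, so they do not show what that array contributed. At the main scaling it was the lowest 99021 array only for hsa-miR-26a-5p (-2.71 against -2.66 and -2.35) and hsa-miR-26b-5p (-3.54 against -3.12 and -2.75). For the others named it was not the lowest.

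**Figure D1:**
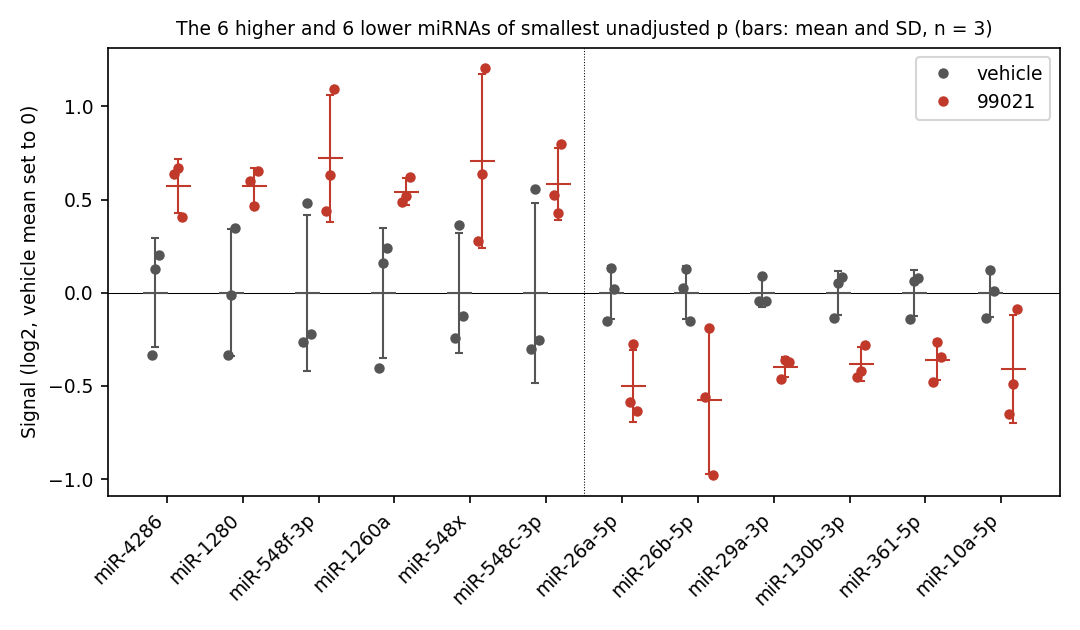
Signal on each array (log2, vehicle mean set to 0) of the 6 higher and the 6 lower miRNAs of smallest unadjusted p, with the mean and SD of 3 arrays per group. No miRNA shown passed the threshold, and the groups overlap for the 3 miR-548 entries and for miR-10a-5p.

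Lists of miRNAs fixed before the data were examined were then compared with the other miRNAs. One list stood out, the entries that overlap structural RNA fragments, mostly pieces of tRNA or similar RNAs that were once named as miRNAs. All 8 of its 8 tested entries were higher in the 99021 arrays, with a median log2 difference of 0.34 and a mean of 0.39. The estimated correlation between the entries was 0.53, so they are not 8 separate measurements. With each array left out in turn all 8 stayed above 0. The median ran from 0.24 without vehicle replicate 1 to 0.49 without vehicle replicate 3, and was 0.57 without 99021 replicate 3 with the shared shift included. The brightest, hsa-miR-720, was at 1.27-fold (log2 difference 0.34, SE 0.17), and hsa-miR-1274b was at 1.26-fold (0.34, SE 0.17). Both depended on single arrays, from 0.21 without vehicle replicate 1 to 0.50 without vehicle replicate 3 for hsa-miR-720 and from 0.20 to 0.47 for hsa-miR-1274b. Without 99021 replicate 3 they were at 0.56 and 0.59, with the shared shift included. The list rose relative to the other miRNAs in limma's camera test with a preset correlation (adjusted p = 1.27e-08 over 12 lists). This was not so with an estimated correlation (adjusted p = 0.402), and fry, which tests a list against no change and not against the other miRNAs, gave an adjusted p of 0.613. The mean of the list minus that of the other miRNAs was 2.93 ± 0.17 in vehicle and 3.37 ± 0.16 in 99021 arrays (log2, SD, n = 3), with no overlap (exact permutation p = 0.1, the smallest that 3 against 3 allows, two-sided). Of its entries, 0 passed over all miRNAs and 3 passed when adjusted over the list alone.

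How far the list's own level differed depended on the scaling, since the median of all tested miRNAs moved from -0.06 to -0.22 without scaling, -0.16 with scaling to spike-in RNAs and -0.52 with the 75th percentile of all human probes. Relative to the spike-ins, the list mean was 0.29 higher and the mean of the other miRNAs 0.15 lower in 99021 arrays (exact permutation p = 0.3 and 0.5). With the percentile over all probes the list's median was -0.17, below vehicle, while its difference from the other miRNAs stayed at 0.39. Of 3101 human probes 228 were kept, so that percentile lies among probes not kept. It scales the arrays by signal near background.

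**Figure D2:**
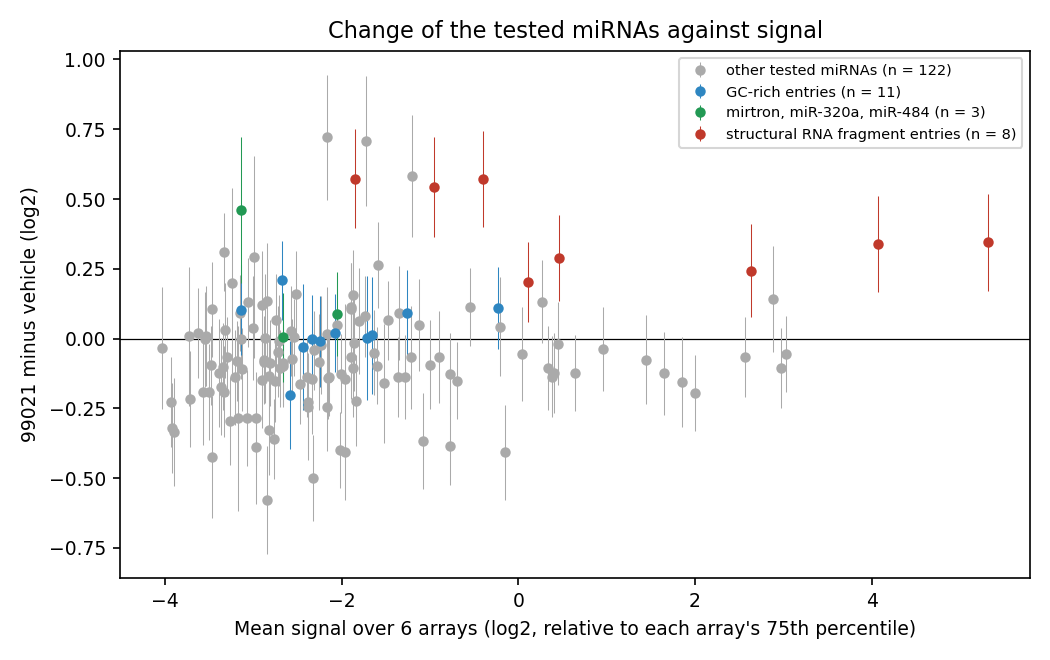
Log2 difference between 99021 and vehicle for each tested miRNA (points, with the standard error as bars) against its mean log2 signal relative to the array's 75th percentile. The 8 structural RNA fragment entries all lie above 0, from 0.20 to 0.57. Their mean signal runs from -1.85 to 5.32, with the largest differences at the dimmer end of that range. Relative to the percentile of all human probes, which lies among probes not kept, their median was -0.17.

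miRNAs listed as maturing without Drosha were compared with the rest because the study's title concerns the Microprocessor. Of 19 such entries on the array 3 could be tested, and all 3 had positive differences. hsa-miR-1225-5p, listed as a mirtron, was at 1.06-fold, hsa-miR-320a at 1.00-fold and hsa-miR-484 at 1.38-fold. hsa-miR-484, named here after its value was seen, was brightest on 99021 replicate 3, at -2.18 on the log2 scale. The other 99021 arrays, at -3.23 and -3.29, lay within the range of the vehicle arrays (-3.61, -3.15 and -3.33). Its difference was 0.46, so most of it came from 1 array. Refitted without that array it was 0.26, which includes the shared shift. The list's median difference was 0.09 and its mean 0.18, short of the threshold (camera adjusted p = 0.498), with 0 entries passing over all miRNAs and 0 adjusted over the list alone. Without vehicle replicate 1 the mean was 0.07, the median 0.0016 and hsa-miR-320a at -0.14. Without 99021 replicate 3 the median was 0.26 with the shared shift included. The list's difference from the other miRNAs, where that shift cancels, was then 0.13 against 0.22 with all arrays. hsa-miR-1225-5p was the only entry of the mirtron list tested, and whether it is made without Drosha here was not tested.

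Families made through Drosha showed no difference past the threshold, and for 6 of the 12 lists the sign of the median turned when 1 array was left out. The let-7 family, which restrains RAS and MYC, had 5 of 7 tested members below 0 with a median of -0.05 (camera adjusted p = 0.807), but 0 of 7 above 0 without vehicle replicate 1 (median -0.12) and 5 of 7 without 99021 replicate 1 (0.06). hsa-let-7a-5p was at 0.963-fold and hsa-let-7f-5p at 0.956-fold, and the let-7 sequences differ by so few bases that signal may be shared between their probes. In the miR-17-92 group 11 of 13 members were below 0 with a median of -0.10 (camera adjusted p = 0.757). Refitted without 99021 replicate 3, with the shared shift included, 13 of 14 were above 0 with a median of 0.037. At the main scaling hsa-miR-19b-3p was still below the vehicle mean of 3.03 on the other 99021 arrays, at 2.81 and 3.00. The miR-15/16 family, which acts on cyclin and BCL2 transcripts, had 3 of 5 below 0 with a median of -0.15, where hsa-miR-16-5p was at 0.874-fold and hsa-miR-15b-5p at 0.899-fold, while camera placed the list above the other miRNAs (adjusted p = 0.958). Without 99021 replicate 3, again with the shared shift, its median was 0.031, and the log2 difference of hsa-miR-16-5p was -0.075 against -0.19. The miR-30 family had 3 of 5 below 0 with a median of -0.06 (camera adjusted p = 0.958, also upward). hsa-miR-30b-5p was at 0.956-fold and hsa-miR-30a-5p at 1.00-fold. The median ran from -0.16 without 99021 replicate 2 to 0.094 without 99021 replicate 3, where 5 of 5 were above 0 with the shared shift included. In the miR-29 family hsa-miR-29a-3p was the 1 member that passed when adjusted over the list alone, 0 passed over all miRNAs, hsa-miR-29c-3p was at 1.05-fold and the list's median was -0.15 (camera adjusted p = 0.525), or -0.29 without vehicle replicate 1 and -0.0069 without vehicle replicate 2. On each 99021 array the miR-29 list lay lower relative to the other miRNAs than on any vehicle array, by -0.13 on average (exact permutation p = 0.1). It was 1 of 3 lists among the 12 whose groups did not overlap, beside the fragment and Drosha-independent lists, where chance gives 10%. Adjusted over the list alone, 0 members passed in each of the other 10 lists tested.

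The miR-10 and miR-196 entries, encoded in the HOX loci, had 4 of 4 members below 0 with a median of -0.28 (camera adjusted p = 0.307), and hsa-miR-10b-5p was at 0.954-fold. The median ran from -0.34 without vehicle replicate 1 to -0.12 without 99021 replicate 1, where 2 of 4 were above 0. Without 99021 replicate 3 the list's difference from the other miRNAs was -0.39 (camera adjusted p = 0.000705, but 0.396 with an estimated correlation). The clusters of miR-99, miR-100 and miR-125 had 3 of 4 members below 0 with a median of -0.16 (camera adjusted p = 0.525), with hsa-miR-99a-5p at 0.797-fold and hsa-miR-125a-5p at 1.00-fold. Their median ran from -0.25 without vehicle replicate 1 to -0.0043 without 99021 replicate 1. Without 99021 replicate 3 their difference was -0.30 (adjusted p = 0.00624, or 0.396 with an estimated correlation). The miR-23/27/24 clusters had a median of -0.14 in 5 members, with hsa-miR-27b-3p at 1.06-fold and hsa-miR-24-3p at 0.906-fold (camera adjusted p = 0.807). Without 99021 replicate 3 their median was 0.031 with the shared shift included. hsa-miR-221-3p was at 0.931-fold, hsa-miR-222-3p at 0.944-fold, and their list with hsa-miR-21-5p had a median of -0.10 in 3 members (camera adjusted p = 0.757), or from -0.19 without vehicle replicate 1 to 0.021 without 99021 replicate 1. The 11 GC-rich entries, whose probes tend to bind RNA less specifically, had a median of 0.01 (camera adjusted p = 0.525), with hsa-miR-3162-5p at 1.08-fold and hsa-miR-4281 at 1.07-fold. Refitted without 99021 replicate 3, with the shared shift included, the median was 0.36 with 11 of 11 above 0. hsa-miR-3162-5p was then at 0.36 against 0.11 on the log2 scale and hsa-miR-4281 at 0.38 against 0.09. How many would lie above 0 without the shift was not counted. The difference from the other miRNAs, where the shift cancels, was 0.23 (camera adjusted p = 0.0264, or 0.849 with an estimated correlation).

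**Figure D3:**
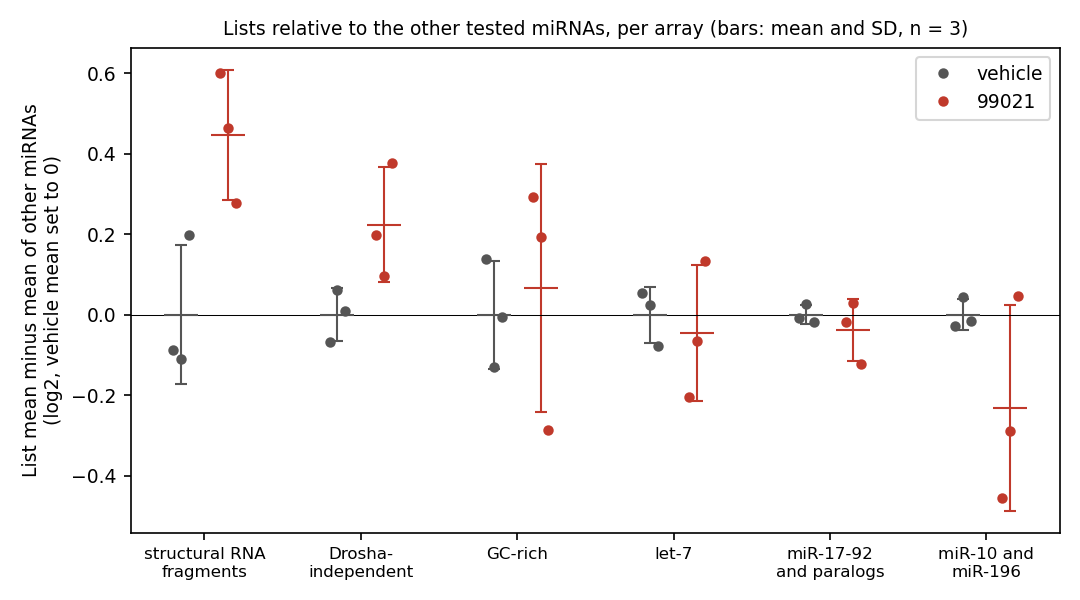
Mean of each list minus the mean of the other tested miRNAs on every array (log2, vehicle mean set to 0), with the mean and SD of 3 arrays per group. Of the 6 lists shown, the fragment list and the Drosha-independent list separate the groups, by 0.45 and 0.22; the miR-29 list, not shown, also does, by -0.13.

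Lists with fewer than 3 tested entries were given as values. In the clusters linked to beta-catenin signalling, hsa-miR-96-5p was at 0.941-fold and hsa-miR-183-5p, detected on 2 of 3 99021 arrays, at 0.933-fold. hsa-miR-181a-5p was at 0.935-fold and hsa-miR-301a-3p, detected on 2 of 3 99021 arrays, at 0.82-fold. The log2 difference of hsa-miR-301a-3p was -0.29, or 0.041 without 99021 replicate 3 with the shared shift included. hsa-miR-34a-5p, a p53 target, was at 0.935-fold and hsa-miR-494-3p of the DLK1-MEG3 locus at 1.03-fold. No entry of the epithelial miR-200 family, the placental C19MC cluster or the blood cell markers was detected on any array. Of 14 entries marking muscle, liver, endothelial, fibroblast or neuronal cells, 1 was detected on any array and 0 could be tested.

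Because scaling within arrays removes a change shared by all miRNAs, the common level was measured before scaling. The median log2 signal over the tested miRNAs was 6.02 ± 0.09 in vehicle and 5.80 ± 0.28 in 99021 arrays (SD, n = 3), a difference of -0.22 within the spread of the 99021 arrays (exact permutation p = 0.2, two-sided). Relative to the spike-in RNAs the difference was -0.15 (exact permutation p = 0.4), and relative to a set of control probes named hur it was -0.14 with no overlap between the groups (exact permutation p = 0.1). Without 99021 replicate 3 the unscaled difference was -0.07. The number of detected miRNAs differed by -10.7 per array (exact permutation p = 0.5), and by 0.33 in the other direction without 99021 replicate 3.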

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

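The criterion used here was loosened after the values were seen. Of 142 viral entries on the array, outside the comparisons above, 11 were detected on any array, and 0 were detected on all 3 99021 arrays at a signal above every vehicle array, which was the criterion first applied. Asking instead for detection on at least 1 99021 array and no vehicle array gave 3 entries, each detected on 1 array. On 99021 replicate 3, the array that stood apart above, hsv1-miR-H1-3p had a signal of 38.9 and hsv1-miR-H7-3p of 36.4. The highest vehicle arrays had 8.28 and 1.00. Viral entries were detected on every array of both groups, 6 to 8 per array, so their detection is not particular to 99021. On 99021 replicate 2, hsv2-miR-H6-5p had 17.5 against 16.4 on the highest vehicle array.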

How the results depend on the processing

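The fixed letter block, the slide row block and the GC trend were chosen after seeing the data. The count of changed miRNAs was 0 in limma and stayed 0 in 20 of 24 alternatives, with 0 to 36 at an unadjusted p under 0.05; it was 0 to 2 with an array left out, 5 with the letter as a random block and 4 with it as a fixed block. Those called with the letter blocks were hsa-miR-548f-3p, hsa-miR-548x, hsa-miR-1260a, hsa-miR-1280 and, with the random block only, hsa-miR-4286. In the fixed block fit the difference rests on the 2 pairs of arrays that share a letter. Replicate numbers did not pair the samples, as deviations of same-numbered arrays correlated between -0.25 and 0.19, and the replicate block gave 0 calls. The fragment list kept its direction and its camera call in 23 of 23 other settings (difference from other miRNAs 0.24 to 0.55, highest adjusted p = 0.00021) and lost the call with an estimated correlation (0.45, adjusted p = 0.402).

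Most other lists lay near 0 and moved around it. The HOX and miR-99 lists were lower in every setting that tested them, by amounts that varied. The causes were not tested. With the percentile over all probes the difference from the other miRNAs was -0.039 for miR-15/16, -0.027 for miR-30 and -0.29 for HOX (camera adjusted p = 0.0384, or 0.902 with an estimated correlation). With normexp it was -0.12 for miR-17-92 (adjusted p = 0.00236, or 0.97 with an estimated correlation), -0.085 for miR-15/16, 0.0037 for miR-23/27/24 and -0.19 for HOX (adjusted p = 0.00688, or 0.97). With total gene signal it was 0.073 for miR-17-92, -0.065 for miR-30, 0.0048 for miR-29, 0.12 for miR-23/27/24 and 0.025 for the miR-221 list. Without a filter, where most miRNAs sit at the floor, it was 0.051 for let-7, -0.044 for miR-17-92, -0.016 for miR-15/16 and -0.021 for miR-30. In that setting it was -0.053 for miR-29, -0.039 for miR-23/27/24, -0.062 for the miR-221 list and -0.12 for HOX. The miR-30 list was at -0.0014 without scaling, -0.0033 with the brightest probe and -0.0101 with detection on all arrays; miR-15/16 was at -0.057 with the last and -0.0041 with the software's detection call. With the fixed letter block miR-15/16 was at -0.028, miR-30 at -0.026 and GC-rich entries at -0.049, and with the GC trend removed let-7 was at 0.0047 and GC-rich entries at -0.042. With an array left out, the ranges were -0.15 to 0.034 for let-7, -0.071 to 0.0075 for miR-17-92, -0.028 to 0.055 for miR-15/16, -0.044 to 0.091 for miR-30, -0.046 to 0.23 for GC-rich entries, -0.39 to -0.12 for HOX and -0.30 to -0.029 for the miR-99 list. Of these, GC-rich, HOX and miR-99 passed camera without 99021 replicate 3, with adjusted p of 0.849, 0.396 and 0.396 at an estimated correlation. Over all alternatives the HOX list's camera adjusted p ran from 0.000705 to 0.973. With an estimated correlation 0 lists passed in any setting in which it was run, and the lowest adjusted p was 0.253.

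The common shift stayed negative in 13 of 13 alternatives, and the difference in detected miRNAs ran from -16.7 to 0.33 with an array left out. With an array left out in turn, 18 of 41 named miRNAs changed sign at least once. Named miRNAs gave 982 comparisons, of which 12 newly passed, 93 changed sign and 877 did neither; no sign changed in a miRNA with an unadjusted p under 0.05 in the main setting. The common shift without a filter has no value because every array's median lay at the floor. A slide or scan block was not run, as there was 1 of each, and list tests with the letter as a random block were not run. Dim miRNAs near background limit what a small difference can show.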

Other observations

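The tests of the fragment list, of the shared letter, of 99021 replicate 3, of GC content, of the unadjusted count and the fragment list over other splits, and of clusters among cluster members alone were chosen after the results were seen; those of the number of calls over splits, of clusters against all mapped miRNAs and of hairpin arms were set before.

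miRNAs encoded close together differed by similar amounts. In 20 pairs within 10000 bases of each other, covering 27 miRNAs, the log2 differences were 0.11 apart on average, against 0.25 for labels permuted over all mapped miRNAs (one-sided permutation p = 0.00258, adjusted p = 0.00774 over 3 tests). When labels were permuted among these 27 cluster members alone, the expected gap was 0.13 and the p was 0.256 (adjusted p = 0.256). Cluster members as a class thus varied little, and whether shared transcription adds to this cannot be told from 20 pairs. The 5 pairs of arms from 1 hairpin were 0.14 apart against 0.24 (one-sided permutation p = 0.134, adjusted p = 0.201), too few to decide.

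The structural RNA fragment entries stood 0.45 further above the other miRNAs in the 99021 arrays. The tables argue against 3 technical explanations as the whole cause: the difference was 0.42 after each array's GC trend was removed, 0.46 after its trend on brightness was removed and at least 0.37 with any one 99021 array left out, each above the larger SD within groups. A biological candidate is that RNAs made without Drosha hold their level while Drosha products fall. It predicts the same of the entries listed as made without Drosha. These stood 0.25 higher relative to miRNAs outside both lists, without overlap, but only 3 entries could be tested. Singly, hsa-miR-484 was at 0.46, hsa-miR-1225-5p at 0.09 and hsa-miR-320a at 0.0048. Most of the difference of hsa-miR-484 came from 99021 replicate 3, as given above. Camera with an estimated correlation gave an adjusted p of 0.973. The fragment list's own mean was 0.29 higher relative to the spike-ins and 0.30 relative to the hur probes (exact permutation p = 0.3 and 0.2). This does not settle whether it held its level, so the candidate remains open. A difference in RNA quality or in small RNA recovery between samples may also raise tRNA fragments and was not tested. Splitting the 6 arrays in the 10 possible ways cannot give a share under 0.05; the real split gave the highest value (1 of 10, 0.45) and the highest other gave 0.39.

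Vehicle and 99021 arrays that share a letter in their names, vehicle 1 with 99021 2 and vehicle 2 with 99021 3, deviated from their group means together (r = 0.49 and 0.46 across miRNAs, which are not independent replicates). These were the 2 highest of 9 pairs, which a random choice of disjoint pairs gives with a share of 0.0556, so chance and a shared culture or day cannot be told apart with 2 pairs. A shared row of the slide was not the cause, since arrays in 1 row correlated at -0.15 on average against 0.17 across rows, and vehicle 2 and 99021 3 lay in different rows. With the letter as a random block 5 miRNAs passed the threshold, as given above.

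The array of 99021 replicate 3 had lower miRNA signal than the other 5. Its unscaled median lay 0.39 below the lowest other array. Relative to the spike-ins it was still 0.14 below, barely more than the SD of 0.13 among the other 5, but relative to the hur control probes only 0.02 below (SD 0.08), so lower labelling or hybridisation of the whole array remains open. The hur controls were added to this rule after the values had been seen. Relative to the 99021 group mean, the dimmest tested miRNAs of 99021 replicate 3 lay 0.18 higher than its brightest, the opposite of a loss of dim miRNAs. That mean includes replicate 3 itself. The values were floored at 0.0502 and held only miRNAs that passed the detection filter. They thus cannot show a loss among miRNAs below these limits, and loss of dim miRNAs to background remains open. Less input RNA or a difference in the sample itself may remain, and no biological explanation was tested.

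Over the 10 splits, the count of calls was 0 in the real split and at most 1 in the others (10 of 10 as large), and the count at an unadjusted p under 0.05 was 14 against at most 42 (2 of 10 as large). With 10 splits no share can fall under 0.05. The split with 42 set vehicle 1, 99021 1 and 99021 2 against the rest. Whether this exceeds what correlated miRNAs give by chance was not tested.

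Across the 144 miRNAs the log2 difference was higher for probes of higher GC content (Pearson's r = 0.22, Spearman's rho = 0.39, permutation p = 1e-04, the smallest 10000 permutations can give; r = 0.13 and rho = 0.34 without the fragment list). miRNAs are not independent replicates. By array, the GC slopes of the groups overlapped, the lowest 99021 slope lying at -0.036 relative to the highest vehicle slope (log2 per 10 percentage points), which does not separate treatment from variation between arrays.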
